A study of Mus musculus with 8 samples.

How the data were processed

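RNA from 8 cultures of bEnd.3 cells, an immortalised mouse brain endothelial line, was sequenced after addition of recombinant Norrin or of vehicle. Per the labels' protocols, 200 ng/ml of Norrin was added 24 h after seeding and the cells were harvested 24 h later. Total RNA was treated with DNase, depleted of ribosomal RNA, made into libraries with a low-input random-primed kit and sequenced in paired ends. The labels name 4 biological replicates in each of 2 groups and say no more of what separated them, so p-values measure the spread between these cultures as they were made. The sample titles call the control vehicle, while a treatment tag calls it untreated and a protocol non-treated. The titles set the groups here.

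The authors deposited 1 table with estimated counts of reads per gene and library, not normalised, in 8 columns. The same table holds an RPKM value per group that the authors made from the 4 replicates, and a fold that is the ratio of the deposited Norrin RPKM to the vehicle RPKM. STAR is named, without a version, per the submitters' processing notes. The genome build, the annotation, the counting tool and whether counting used strand are not given in the sources used here, so antisense, overlapping and near-identical genes are uncertain and no coordinates are printed. Of 123616 counts, 763 were not whole and 635 of them changed by over 0.01 on rounding, by at most 0.5. Counts were rounded to whole numbers before any test.

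The table held 15452 rows with a gene name and 1 row without, which carried only a fold of 3 and no counts and was left out. Another 20 rows are named by dates, as spreadsheets turn some symbols into, and 18 rows share a tRNA name. These were kept as separate rows and none is named in the results. The lowest deposited vehicle RPKM was 0.1 and 0 genes lay below it, while 439 genes had a Norrin RPKM below 0.1. The rows therefore appear to be selected on the vehicle value alone, so a gene silent under vehicle and induced by Norrin would not be in the table used. Total counts ran from 12463942 to 15220576 per library.

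Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, robust quasi-likelihood fit, two-sided test), with Benjamini-Hochberg adjustment over 13666 genes and a threshold of 0.05 on the adjusted p. The filter left out 1786 genes for low counts. Levels are CPM, a gene's count relative to the library's total count scaled by TMM, as mean ± SD of n = 4. Log2 fold changes are Norrin over vehicle with their standard error (SE). The common dispersion was 0.0124, a coefficient of variation of 11.2% between replicates. A level equal to 3 counts lay between 0.197 and 0.241 CPM, which covers counting error only. The edgeR step was tested on simulated data with 13666 genes, this comparison's means and library sizes. It recovered 22% of 50 genes changed by 1.2-fold, 50% at 1.5-fold, 76% at 2-fold and 98% at 4-fold, with 10 false calls among 135.

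Before the data were examined, 33 gene lists were fixed, with 614 entries of which 461 matched a row of the table. Matching went by symbol, then by older names in a RefSeq gene table of the GRCm38 assembly or in the file. The names listed for mitochondrially encoded respiratory genes matched 0 rows, so that list was not analysed here. The table did hold rows for such genes under other names, among them ATP8 and COX3, which the matching missed. The 28 lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. The rule for named genes was also fixed then. It takes the Norrin receptor genes, Ctnnb1 and Axin2, up to 4 members past the threshold in each list, and all such members of the Wnt feedback and of the brain endothelial beta-catenin lists. It adds the 10 largest rises and falls among genes with non-overlapping groups, at least 1 CPM in the higher group and an established symbol, and up to 2 abundant members of lists without a call. Some genes that this rule takes are not reported here.

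Alternatives fixed before the data were examined were DESeq2 size factors, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a threshold of 0.01, and the other list tests. Removal of trends with GC content or transcript length, and a minimum RPKM of 0.1 in both groups, were added after seeing the data. GC content was known for 90.5% of tested genes. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom ran from 5.68 to 15.42.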

Results

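Gene expression was measured by RNA-seq in bEnd.3 cells, a mouse brain endothelial line. Norrin is a secreted ligand of the receptor Frizzled-4 that activates beta-catenin signalling in endothelium. Cells received recombinant Norrin at 200 ng/ml or vehicle for 24 h, with 4 libraries per group. Total counts per library ran from 12463942 to 15220576 under vehicle and from 13445380 to 14905863 under Norrin.

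The comparison asked which genes Norrin induced in these cells. Axin2, a negative regulator and classical target of beta-catenin signalling, rose 18.7-fold, from 0.360 ± 0.214 to 6.71 ± 1.04 CPM (SD, n = 4 per group). Il6, encoding the cytokine interleukin 6, rose 11.6-fold, from 0.784 ± 0.438 to 8.94 ± 2.41 CPM. The purinergic receptor gene P2ry1 rose 5.41-fold and Bmx, an arterial kinase gene, rose 2.86-fold to 39.0 ± 7.89 CPM. The cadherin gene Cdh6 fell by 1.26 on the log2 scale, from 14.1 ± 1.76 to 5.87 ± 1.17 CPM.

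In all, 164 genes rose and 132 fell among 13666 tested (edgeR, adjusted p under 0.05), or 2.17%. At an unadjusted p under 0.05, 1548 genes passed. Of the 296 called genes, 28 rose and 7 fell by 2-fold or more. The 4 Norrin libraries lay wholly above or below the 4 vehicle libraries in 275 of them, against 7.01% of all tested genes and 2.86% by chance. The called genes were chosen on the same libraries, so their non-overlap is no separate evidence. Over 450 genes called without it, Norrin replicate 4 moved 0.64 as far from vehicle on the log2 scale as the other Norrin libraries did. Norrin replicates 1, 2 and 3 moved 0.94, 1.03 and 1.00, over 206, 214 and 239 genes called without each. Their reference means included replicate 4. Vehicle replicates 1 to 4, left out likewise, gave 0.15, 0.12, 0.08 and 0.08. Without Norrin replicate 4, 235 genes rose and 217 fell, 452 in all, of which 275 were among the 296. Without Norrin replicate 1, 122 rose and 84 fell.

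**Figure D1:**
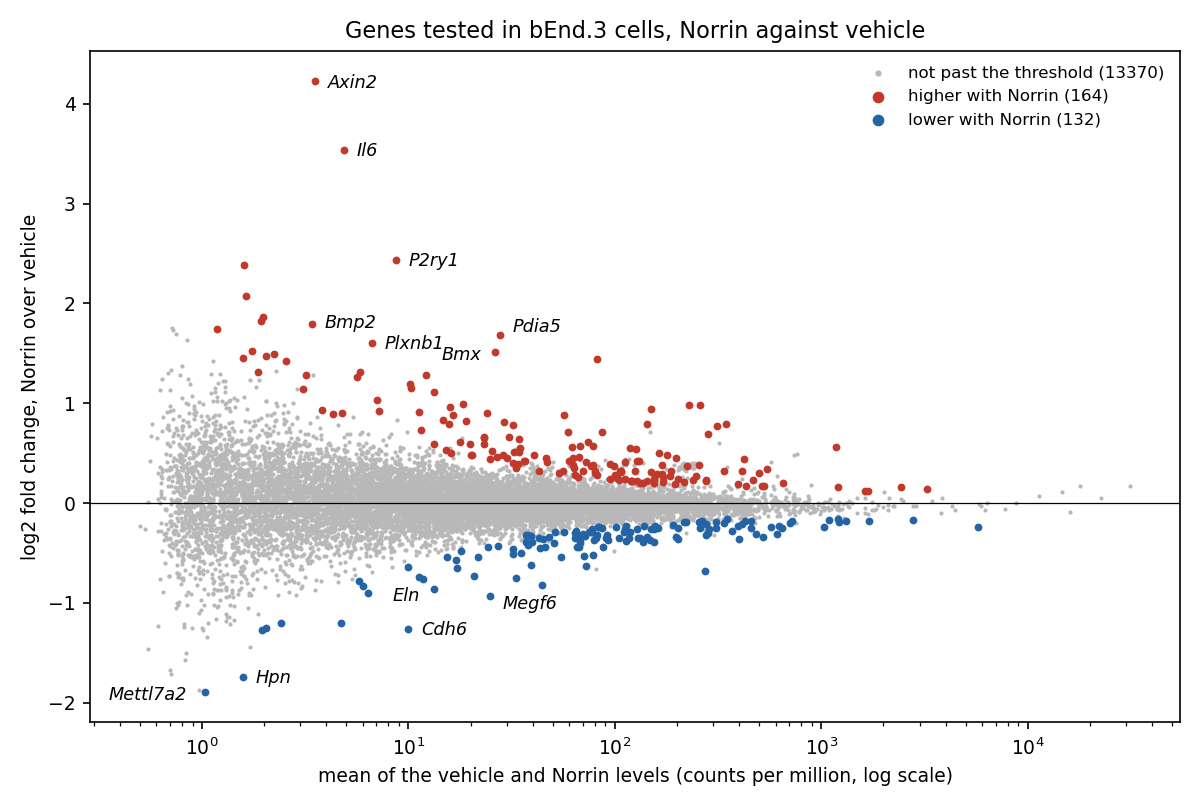
Log2 fold change (Norrin over vehicle) of each of the 13666 genes tested, against the mean of both groups' levels in CPM on a log axis; red points rose (164), blue points fell (132) and grey points did not pass the threshold. Axin2 at 4.23 and Il6 at 3.54 lie above all other called genes.

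The largest rises after Axin2 (log2 4.23 ± 0.35 SE, adjusted p = 1.18e-09) and Il6 (3.54 ± 0.32, 1.70e-08) were in P2ry1 (2.44 ± 0.19, 3.46e-10), the phosphatase gene Dusp2 (2.38 ± 0.45, 0.0016), the adhesion receptor gene Adgrg6 (2.08 ± 0.40, 0.00186) and the transcription factor gene Nfatc2 (1.82 ± 0.39, 0.00657). Levels under vehicle were low for Dusp2 (0.521 ± 0.342 CPM), Adgrg6 (0.619 ± 0.193 CPM) and Nfatc2 (0.833 ± 0.510 CPM). Bmp2, a secreted growth factor gene, rose by 1.79 ± 0.28 to 5.26 ± 1.11 CPM. Pdia5, a protein disulfide isomerase gene, rose 3.22-fold, from 13.1 ± 1.6 to 42.4 ± 4.39 CPM, and the semaphorin receptor gene Plxnb1 rose 3.04-fold. Rp1 also passed, with log2 1.75 ± 0.44, at only 1.83 ± 0.384 CPM under Norrin. Its call was lost without vehicle replicate 1 or 4 or Norrin replicate 1, 2 or 3, where the adjusted p was 0.0736 to 0.126.

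The largest falls reported here were in Mettl7a2 (−1.89 ± 0.47), the serine protease gene Hpn (−1.74 ± 0.40) and Papln (−1.27 ± 0.33), all below 3 CPM under vehicle, followed by Cdh6 (−1.26 ± 0.17) and Klhl6 (−1.20 ± 0.25). Megf6, Nepn, the elastin gene Eln and Flrt2 fell by 0.93, 0.90, 0.86 and 0.82 on the log2 scale, Flrt2 from 56.6 ± 6.28 to 31.9 ± 2.41 CPM. Several of these low genes lost their call with 1 library left out, while their log2 fold changes stayed near those with all libraries. In the fits that lost the call, Papln was at −1.14 to −1.39, Mettl7a2 at −1.70 to −1.98 and Hpn at −1.54 and −1.66. Papln lost its call with any 1 of the 8 libraries left out (adjusted p up to 0.141). Mettl7a2 kept it only without vehicle replicate 2 or 3 (up to 0.112 otherwise), and Hpn lost it without Norrin replicate 1 (0.0737) or vehicle replicate 2 (0.0521).

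**Figure D2:**
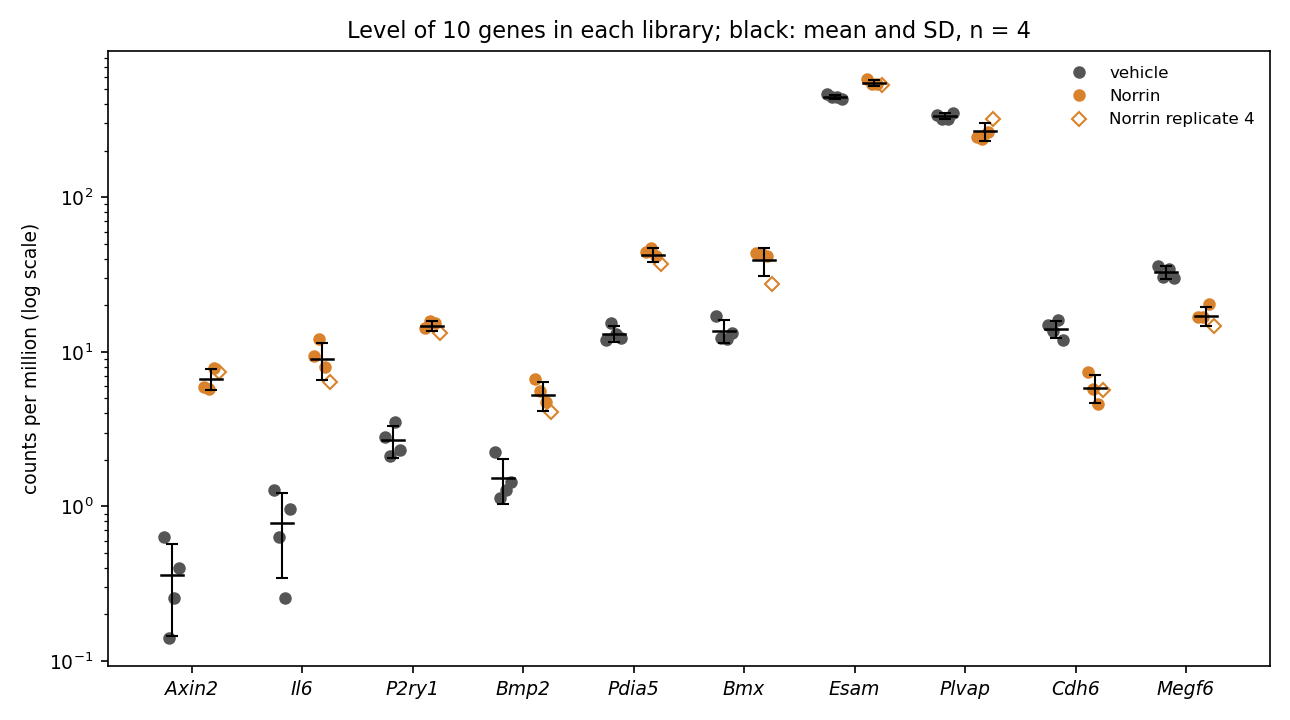
Level of 10 genes in each library, in CPM on a log axis, under vehicle (grey) and Norrin (orange; open diamonds are Norrin replicate 4), with mean and SD of n = 4 in black. Axin2 lay at 5.76 to 7.83 in every Norrin library and at 0.142 to 0.638 under vehicle, while Plvap, which did not pass the threshold, lay nearest to vehicle in Norrin replicate 4.

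Among receptor genes, Fzd4 was at 82.7 ± 1.5 CPM under vehicle and 76.0 ± 2.38 CPM under Norrin (log2 −0.12 ± 0.06, adjusted p = 0.463). The coreceptor gene Lrp5 fell by 0.25 on the log2 scale (0.002), and Lrp6 did not pass (0.06 ± 0.05, 0.796). Tspan12, encoding a tetraspanin of the Norrin receptor complex, rose by 0.49 ± 0.11 (0.0151). Ctnnb1, the beta-catenin gene, fell by 0.24 on the log2 scale from 1119 ± 37.7 CPM (8.93e-05), and Fzd6 rose by 0.39 ± 0.06. Ndp, the gene of Norrin itself, was not analysed here. In the list of receptor and Wnt components, 2 of 22 tested members rose, 2 fell and 18 did not pass (adjusted over the list alone, 2 rose and 3 fell; camera adjusted p = 0.421). The call for Tspan12 was lost without Norrin replicate 1 or vehicle replicate 2, 3 or 4 (0.053 to 0.0648).

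Of 20 genes listed as Wnt feedback or classical targets, 12 were in the table and 11 could be tested. Axin2 rose and 10 did not pass, also when adjusted over the list alone. Ccnd1 (−0.02, 95% interval −0.22 to 0.17), Myc (0.11, −0.11 to 0.32) and Znrf3 (0.11, −0.14 to 0.36) had intervals below a 2-fold rise. Apcdd1 was at −0.39 (−0.86 to 0.07). The list had a median of −0.02 and a mean of 0.40 on the log2 scale (camera adjusted p = 0.662, upward). Among genes tied to beta-catenin in brain and retinal endothelium, Sox17 rose by 0.38 ± 0.06, Sox18 fell by 0.34 on the log2 scale and 12 of 14 did not pass (adjusted over the list alone, also 1 rose and 1 fell). This list's median was −0.03, its mean 0.08, and camera pointed down (adjusted p = 0.992). Of 20 Wnt ligand and R-spondin genes, 4 were in the table, and 0 of 3 tested were called by edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; 1 over the list alone; camera 0.547). Wnt5a was at 0.09 ± 0.13 and Rspo3 at −0.25 ± 0.20. The third, Wnt5b, named after its values were seen, was at 0.87 ± 0.25 (adjusted p = 0.0682), and 1 member passed without vehicle replicate 2 or Norrin replicate 4.

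Among junction genes, 2 of 15 rose, among them Esam, an endothelial adhesion molecule gene (0.31 ± 0.04, adjusted p = 1.79e-05), and 13 did not pass. Adjusted over the list alone, 2 also rose. The list's median was −0.01 and its mean 0.12 (camera adjusted p = 0.326, upward). Of 16 transporter and receptor genes of the blood-brain barrier, the insulin receptor gene Insr (0.57 ± 0.07, 5.09e-06) and Slc3a2, a subunit of amino acid transporters (0.29 ± 0.06, 0.00681), rose (3 over the list alone; camera 0.167). Slc3a2 lost its call without Norrin replicate 2 (0.0634; 0.000128 to 0.0634 over all alternatives).

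Of 10 genes of caveolae, the membrane pits that carry vesicular transport, 3 fell and 7 did not pass by edgeR, while DESeq2 called 6 and limma-voom 5. Sdpr (Cavin2) fell by 0.30, Ptrf (Cavin1) by 0.19 and Ehd2 by 0.20 on the log2 scale, 9 of 10 members lay below 0, and 7 were lower adjusted over the list alone. Without Norrin replicate 4, 5 members passed. The list was lower by camera (adjusted p = 6.47e-05), with an adjusted p = 0.0916 with an estimated correlation. For genes of fenestrated endothelium, 0 of 9 were called by edgeR (5 at an unadjusted p under 0.05 and 5 over the list alone, all lower; 2 by DESeq2, 1 by limma-voom, 2 without Norrin replicate 4). That list was lower by camera (0.00857), with an adjusted p = 0.414 with an estimated correlation. Plvap, encoding the protein of fenestral diaphragms, was at 334 ± 14 CPM under vehicle and 268 ± 36.2 CPM under Norrin (−0.32 ± 0.08, 0.0569). Without Norrin replicate 4 it passed, at −0.42 (7.86e-07; 7.86e-07 to 0.208 over all alternatives). Igfbp3 was at −0.20 ± 0.13 (0.667). Without vehicle replicate 1 the fenestration list did not pass (0.0956; 0.000589 to 0.414 over all alternatives).

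Endothelial subtype genes moved in both directions. The arterial gene Bmx rose by 1.52 ± 0.14 and the arterial transcription factor gene Sox17 by 0.38 ± 0.06. The venous genes Ephb4 and Nr2f2 fell by 0.34 and 0.31 on the log2 scale, and 8 of 12 members did not pass (4 higher and 3 lower over the list alone; camera adjusted p = 0.507). The list pools arterial and venous genes, and camera tests for a shift in a shared direction, so camera could miss opposite shifts. Without Norrin replicate 4, 7 members passed. Nr2f2 lost its call without vehicle replicate 4 (0.0606; 0.000842 to 0.0606 over all alternatives). Among 16 tip-cell and angiogenesis genes, the Notch ligand gene Dll4 (0.48 ± 0.06), Unc5b (0.26 ± 0.05) and Cd34 (0.17 ± 0.04) rose (4 higher and 1 lower over the list alone; camera 0.262). In the Notch list, Dll4 and Jag2 (0.46 ± 0.08) rose and Dll1 fell by 0.37 on the log2 scale, of 14 tested (2 and 2 over the list alone; median 0.02, mean 0.04, camera downward, 0.95). Jag2 lost its call without Norrin replicate 1 or any 1 vehicle library (0.0513 to 0.078). Of 20 pan-endothelial genes, Esam and Cd34 rose, Sox18 and Egfl7 fell (by 0.16 on the log2 scale for Egfl7) and 16 did not pass (2 and 6 over the list alone; camera 0.279). Cd34 lost its call without vehicle replicate 2 or 3 or Norrin replicate 1 or 4 (0.0556 to 0.165). Egfl7 kept it only without vehicle replicate 1 or Norrin replicate 4 (up to 0.151 otherwise), so 2 of the list's members passed without vehicle replicate 2 or 3 or Norrin replicate 1.

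**Figure D3:**
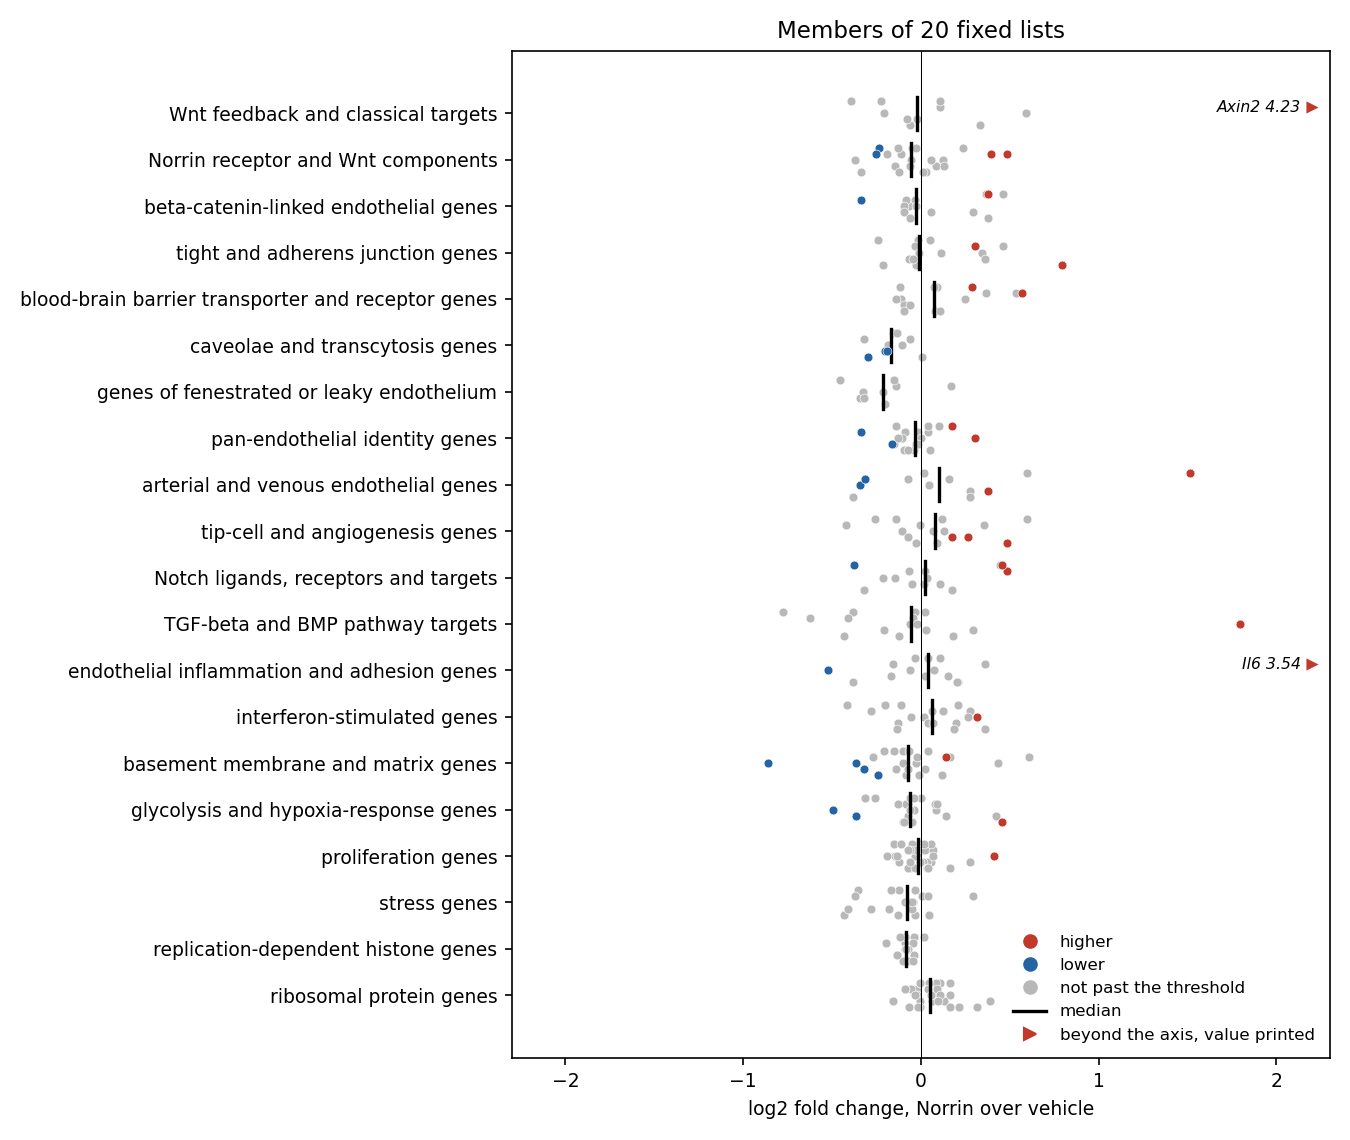
Log2 fold change (Norrin over vehicle) of each tested member of 20 fixed lists; red members rose, blue fell, grey did not pass the threshold, black bars are medians, and triangles mark values beyond the axis. Axin2 (4.23) and Il6 (3.54) stand apart from the other members of their lists, and 9 of 10 caveolae genes lie below 0.

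Among matrix genes, 4 of 23 fell and 1 rose. Fibronectin (Fn1) fell by 0.24 on the log2 scale from 6213 ± 113 CPM, Timp3 by 0.36, Fbln5 by 0.32 and Eln by 0.86, while Col18a1 rose by 0.14 ± 0.04. The other 18 did not pass. Adjusted over the list alone, 2 of the 23 were higher and 9 lower. The list was lower by camera (adjusted p = 0.0251), with an adjusted p = 0.592 with an estimated correlation. It did not pass without vehicle replicate 1 or 2 or Norrin replicate 1 or 3 (0.0724 to 0.144), nor with the GC trend removed (0.235; 0.000294 to 0.592 over all alternatives).

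Of 15 inflammation and adhesion genes, Il6 rose and Selp, the P-selectin gene, fell by 0.52 on the log2 scale (2 and 2 over the list alone; camera adjusted p = 0.718). Selp lost its call without Norrin replicate 1 or vehicle replicate 1 or 2 (0.0504 to 0.121). In the interferon list, Stat2 rose by 0.32 ± 0.08 and 18 of 19 did not pass (1 over the list alone; camera 0.662). Stat2 kept its call only without vehicle replicate 3 or Norrin replicate 4 (up to 0.141 otherwise), and without Norrin replicate 4, 3 members passed and the list was higher (0.00887; 0.00887 to 0.993 over all alternatives). With all 8 libraries the list had an adjusted p = 0.912 with an estimated correlation, which was not computed without Norrin replicate 4. For 13 antigen presentation genes, 0 were called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, 0 over the list alone; camera 0.983). H2-D1 was at 0.01 ± 0.06 and B2m at 0.03 ± 0.06.

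Of 16 TGF-beta and BMP genes, Bmp2 rose and 15 did not pass (3 members passed by DESeq2, 2 by limma-voom and 2 without vehicle replicate 1 or Norrin replicate 4; 1 higher and 3 lower over the list alone; camera adjusted p = 0.2, and 0.0422, downward, without Norrin replicate 4; 0.0422 to 0.592 over all alternatives, the highest being the adjusted p with an estimated correlation and all 8 libraries). Of 11 YAP targets, Cyr61 rose by 0.24 ± 0.06 (0 members passed by limma-voom; 1 over the list alone; camera 0.718), and it kept its call only without vehicle replicate 2 (up to 0.196 otherwise). In the glycolysis and hypoxia list, Egln3 and Pfkfb3 fell by 0.37 and 0.50 on the log2 scale and Pfkp rose by 0.45 ± 0.09, of 22 tested (1 and 3 over the list alone; camera 0.167, and 0.0422, downward, without Norrin replicate 4; 0.0422 to 0.801 over all alternatives; adjusted p = 0.658 with an estimated correlation and all 8 libraries). Of 34 proliferation genes, Tyms rose by 0.41 ± 0.09 and 33 did not pass, also over the list alone (camera 0.718).

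In the stress list, 0 of 20 members were called by edgeR (5 at an unadjusted p under 0.05, 3 by DESeq2, 1 by limma-voom, 1 without Norrin replicate 1 or 4; 3 lower over the list alone). The list was lower by camera (adjusted p = 0.0078), with an adjusted p = 0.374 with an estimated correlation, and did not pass without vehicle replicate 1 (0.116; 0.00278 to 0.374 over all alternatives). The chaperone genes Hsp90b1 and Hspa5 were at −0.05 ± 0.03 and 0.04 ± 0.04. Of 19 cholesterol genes, 0 were called by edgeR (2 at an unadjusted p under 0.05, 1 each by DESeq2, by limma-voom and without Norrin replicate 3; 2 lower over the list alone; camera 0.2), with Srebf2 at −0.01 ± 0.06. Of 17 immediate early genes, 0 were called (3 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, 0 over the list alone; camera 0.662), with Jund at 0.03 ± 0.07 and Klf2 at −0.10 ± 0.09.

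Lists for RNA class and other cell types held no called gene. Of 30 ribosomal protein genes, 0 were called (1 at an unadjusted p under 0.05; camera adjusted p = 0.662), with Rpl8 at −0.07 ± 0.04 and Rpl4 at 0.00 ± 0.04. Of 16 histone genes, 0 were called (1 at an unadjusted p under 0.05, 1 without vehicle replicate 3), 15 lay below 0 and the list was lower by camera (0.0165), with an adjusted p = 0.658 with an estimated correlation. It did not pass without vehicle replicate 1, 2 or 4 or Norrin replicate 3 (0.0588 to 0.345), nor with the GC trend removed (0.185; 0.000352 to 0.658 over all alternatives). Hist1h1c was at −0.04 ± 0.05 and Hist1h1d at −0.08 ± 0.05. Of 11 nuclear non-coding RNAs, 0 were called (0 at an unadjusted p under 0.05; camera 0.718), with Malat1 at 0.07 ± 0.12 and Rpph1 at −0.06 ± 0.03. DESeq2, limma-voom and adjustment over the list alone also called 0 in these 3 lists.

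Markers of mural cells, fibroblasts, astrocytes, microglia, neurons and lymphatic endothelium had 15 tested members in 6 lists and 0 were called by edgeR, DESeq2 or limma-voom (3 at an unadjusted p under 0.05; adjusted over the list alone, 1 astrocyte marker was lower and 1 neuron marker higher). Of the listed markers, 6 of 14, 5 of 12, 3 of 10, 3 of 12, 4 of 10 and 2 of 7 were in the table. Camera gave an adjusted p = 0.712 for mural and 0.95 for neuron markers, the latter upward with a median of −0.08. The other 4 lists were too short to test. Acta2 and Anpep were at 2.65 ± 1.39 and 3.00 ± 1.03 CPM under vehicle, Pdgfra and Fbln1 at 4.08 ± 1.86 and 2.47 ± 1.13 CPM. Gja1 was at 50.9 ± 3.06, Cd68 at 94.3 ± 4.60, Gad2 at 63.8 ± 2.46, Nefl at 37.5 ± 1.58, Flt4 at 191 ± 5.99 and Lyve1 at 47.5 ± 1.96 CPM. Fgfr3, 1 of 2 tested astrocyte markers, was at 1.24 ± 0.337 CPM under vehicle and 0.417 ± 0.522 CPM under Norrin (adjusted p = 0.235, and 0.011 without Norrin replicate 4; 0.011 to 0.494 over all alternatives).

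The authors' deposited table gives 323 folds of 2 or more and 569 of 0.5 or less. Its rows have a vehicle RPKM of at least 0.1 and no such minimum under Norrin, which favours falls among low genes. The 2 counts therefore cannot be read as more genes repressed than induced. The test on replicates called 37 of these 892 genes, and 701 had too few counts to be tested. Among the 20 largest folds in the authors' deposited table, 15 belonged to small RNAs and 2 were called by edgeR. Axin2 had a deposited fold of 21.3, from an RPKM of 0.123 under vehicle to 2.63 under Norrin.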

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

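The tests of depth, of position and of residuals for Norrin replicate 4 were chosen only after its smaller response was seen. Across 178 groups of 4 libraries, 13 held 1 library far from the other members, where chance gives about 1 in 20. Among genes that rose or fell, Esam was at 585 CPM in Norrin replicate 1 (others 536 to 542), Dll1 at 51.8 in Norrin replicate 2 (61.2 to 62.0) and Fbln5 at 269 in Norrin replicate 2 (238 to 242). Cyr61 was at 109 CPM (100 to 102) and Bmx at 27.3 (41.5 to 43.9) in Norrin replicate 4, and Klhl6 at 1.54 in Norrin replicate 3 (3.21 to 3.38). Under vehicle, replicate 1 stood apart for Pfkfb3 at 35.5 CPM (42.2 to 43.1) and Rpph1 at 8210 (7830 to 7890). Replicate 2 did so for Plxnb1 at 3.89 (3.05 to 3.15) and Flrt2 at 65.9 (52.3 to 54.6), and replicate 3 for Hpn at 1.48 (2.65 to 2.83), Rpl8 at 1050 (1130 to 1140) and Hist1h1d at 331 CPM (371 to 374).

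Norrin replicate 4 showed 0.64 of the response of the other Norrin libraries over 450 genes called without it, and lower sequencing depth is argued against, since its total count of 13445380 lay 1.8% below the lowest of the others. Vehicle RNA mixed into this library is a candidate explanation that stays open. Genes that rose 2-fold or more sat at 0.56 of the way from vehicle to the other Norrin libraries (95% interval 0.49 to 0.72). As dilution would predict, this was near the 0.48 (0.39 to 0.56) of smaller rises and the 0.61 (0.50 to 0.66) of falls. These intervals come from resampling genes within this library. They do not measure spread between cultures, and genes are not independent replicates. A second test, added after the position test, asked whether responding genes scattered more around 1 shared position than matched genes that did not respond. The ratio was 1.76 with tagwise and 2.15 with trended dispersion, above every other Norrin library, which by the terms first set argued against mixing, but Norrin replicate 2, at full response, gave 1.70 and 1.87. An F test of that gap, added after these values were seen, did not separate both libraries with either dispersion, and with it mixing and a weaker response of this culture to Norrin, which was not tested, cannot be told apart.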

How the results depend on the processing

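GC and length trends and the RPKM minimum in both groups were chosen after seeing the data. Of the 296 called genes, 269 to 296 were also called under each other normalisation, filter, tool or trend removal, and none changed sign in any alternative. DESeq2 called 404 genes, 295 of them shared, and gave no adjusted p for 531. At an adjusted p under 0.01, 99 genes rose and 72 fell. With each library left out in turn, 110 to 235 genes rose and 84 to 217 fell. Each of these fits had fewer samples, and whether that set the lowest counts was not tested. Both highest counts came without Norrin replicate 4. Fixed lists that were higher numbered 0 in the main test (1 at an unadjusted p under 0.05, 0 by camera after DESeq2 or limma-voom), 0 to 1 with libraries left out, and 1 by fry, the junction list (adjusted p = 0.0464). Lists that were lower numbered 5, 1 to 7 with libraries left out, 3 with the GC trend removed, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 2 by fry, caveolae (0.00389) and stress genes (0.0464); the cause was not tested. Log2 fold change across genes had a Spearman correlation of −0.15 with GC content and −0.03 with transcript length, and genes are not independent replicates. Plvap passed by DESeq2 (0.000588) and limma-voom (0.0335), and the glycolysis and hypoxia list was lower after limma-voom (0.0434). Cd34 and Egfl7 did not pass with the GC trend removed (0.0612 and 0.161), Cyr61 without a filter (0.0531) or by limma-voom (0.0539), and Mettl7a2 by limma-voom (0.0546).

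With the replicate number as a block, 402 genes were called, 295 of them shared, 214 higher and 188 lower, with 0 lists higher and 5 lower. Whether the numbers pair the samples is not settled. Same-numbered libraries deviated with correlations of −0.02, 0.02, 0.04 and 0.08. Vehicle replicates 1 and 2 correlated best with another number, and replicates 3 and 4 with their own. In that fit Plvap (0.000287) and Igfbp3 (0.00877) also passed.

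Depth limits low genes, of which 1786 had too few counts to test. At this depth, replicate spread and group size together, simulated 1.2-fold changes were found in 22% of genes.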

Other observations

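The genes in this part lie outside the fixed lists or rule and were chosen after their values were seen, and the tests of depth, of table membership and of the geometric mean were also chosen after the results were seen. The smallest adjusted p of all genes belonged to Npnt, the gene of the matrix protein nephronectin, which rose from 174 ± 12.3 to 342 ± 6.01 CPM (SD, n = 4; log2 0.98 ± 0.05 SE, adjusted p = 1.06e-13). The water channel gene Aqp1 rose by 0.95 ± 0.06 and Myh10, a non-muscle myosin gene, by 0.56 ± 0.04, while Mest fell by 0.68 on the log2 scale. Single genes that also rose were Il6ra (2.22-fold), Stat3 (0.42 ± 0.06), Cebpd (0.65 ± 0.13), Sbno2 (0.37 ± 0.08), Arid5a (0.88 ± 0.14) and Jak3 (0.45 ± 0.11), with no test of them as a group. Jak3 lost its call without vehicle replicate 1 or 4 or Norrin replicate 1, 2 or 3 (adjusted p up to 0.131), and the other genes of this paragraph kept theirs with any 1 library left out (up to 0.0337).

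Calcrl and Ramp2, which together encode the adrenomedullin receptor, fell by 0.36 and 0.31 on the log2 scale from 448 ± 21.8 and 536 ± 38.3 CPM, and the endothelial gene Clec14a fell by 0.63. The guidance gene Slit2 and the matrix gene Thbs1 rose by 0.71 ± 0.08 and 0.55 ± 0.07.

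The count of 296 called genes can be set against other groupings of the libraries. Of all 35 splits into 4 and 4, 1 gave as many calls, the real one, which is the fewest possible. The highest other split gave 2. This argues against chance at a share of 0.05 without excluding it. Each other split put Norrin and vehicle libraries together, so any Norrin effect added to the spread within its groups.

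Axin2 rose while other Wnt feedback genes did not pass. Against too little depth to see a 2-fold rise in the other members, 9 of the 10 other tested members had a 95% interval below a 2-fold rise, with Nkd2 the exception (0.786 to 2.88-fold). Of the 20 listed genes, 8 had no row in the table used and 1, Lef1, had too few counts to test, so whether these rose stays open, and low expression under vehicle was not shown to be the reason. A response limited to Axin2 at 24 h of Norrin was not tested.

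Large deposited folds of low-count genes had a median of 5 counts per library, against 188 for all genes. Whether the libraries share these changes stays open for most, since 701 of the 892 folds of 2 or more in either direction had too few counts to test, and the replicate test called 37 of the other 191. The values fit group RPKMs that are geometric means in which a library with no reads enters at a small floor, a candidate explanation: 99.3% of 458 genes with a 0 in 1 group lay within 0.5 log2 of a mean floored at 0.001, against 0% for an arithmetic mean. Mir6956, with counts of 0, 0, 4 and 6 under vehicle and 5, 9, 1 and 3 under Norrin, had a deposited fold of 99.0 and 1.73 by mean counts.

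Of 9350 genes with at least 100 counts per library on average, 47 had a deposited fold over 0.3 log2 from that of the counts, among them Stx3 with 2.26 deposited and 1.19 by counts. The number of genes at 0 was 69.5 ± 18.2 under vehicle and 188 ± 21.9 under Norrin (SD, n = 4). An exact permutation test gave p = 0.0286, the smallest possible, and 0.229 adjusted over 8 measures. The table's rows have a vehicle RPKM of at least 0.1 and no such minimum under Norrin, which limits zeros under vehicle alone. The test therefore cannot tell an effect of Norrin from this selection.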
